A study of Mus musculus with 13 samples.

How the data were processed

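Single-end RNA sequencing of total RNA was analysed from 13 libraries: 12 of mouse pre-iPSCs (WT and Kdm3b KO at day 0, day 2 and day 10 of AA+2i, with 2 replicates each, lettered A and B) and 1 of ESCs. Per the labels' protocols, cells were kept in ESC medium with 15% fetal bovine serum and LIF, ascorbic acid was given at 50 µg/mL with GSK3 and MEK inhibitors, and the cultures carried to day 10 were split at day 4. The 4 day 0 libraries are titled DMSO while their treatment label names AA+2i. They were read, from title and time point, as the untreated start of the time course. The ESC library also carries the treatment label AA+2i, with time point 0hr, and the growth protocol says with or without these compounds, so its treatment is uncertain. The labels do not say whether replicates A and B were separate cultures.

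Per the submitters' processing notes, reads were aligned with Bowtie2 to mm9 and counted per gene with RSEM, and the deposited values are RSEM expected counts, which share a read that fits several transcripts between them. The aligner and counting versions are not given in the sources used here. In each library 35.0 to 43.8% of the gene values lay more than 0.005 from a whole number. The files hold 20325 genes, all with mRNA accessions, so that noncoding genes are not analysed here. Genes with near-identical copies share reads: Sprr2a1 and Sprr2a2 carry identical values and are treated as uncertain. Symbols are given as in the files, with the current symbol beside 2 of them.

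Expected counts were rounded and tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 in a single fit over the 6 pre-iPSC groups, with filterByExpr (14324 genes, holding at least 99.9% of the counts of each library), TMM factors and contrasts between groups. The ESC library, having no replicate, entered no test. Genes with a Benjamini-Hochberg false discovery rate (FDR) under 0.05 were called changed, with no fold threshold. The common biological coefficient of variation was 0.266 and the fit left 6 residual degrees of freedom. The comparisons were day 2 and day 10 against day 0 and day 10 against day 2 within each genotype, KO against WT at each day, and the interactions of genotype with day 2 and day 10. Mean CPM used TMM-scaled library sizes, and log2 CPM a prior count of 2.

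A total of 26 gene lists was fixed, of which 24 were tested as lists, and 433 of the 447 list entries were found in the files. The 24 covered naive and general pluripotency, fibroblast, epithelial, germline, two-cell-stage, imprinted, H3K9 methylation, DNA methylation, ERK, Wnt, cell cycle, cell cycle inhibitor and p53, interferon, hypoxia, cholesterol, primitive endoderm, trophectoderm, primed epiblast, neural, keratinocyte-like, immune, endothelial and stress genes. The other 2 lists, reprogramming factors and sex-linked genes, are reported gene by gene. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 24 lists of a comparison, and again with an estimated correlation and with fry, which asks whether a list's genes move one way on balance without comparing them to other genes. Of the 94 camera calls, 16 also passed with an estimated correlation: germline and interferon genes in WT at day 10 against days 0 and 2, in KO against WT at day 10 and in the day 10 interaction, trophectoderm markers in WT at day 10, in KO between days 2 and 10, in KO against WT at day 2 and in the day 2 interaction, naive genes in KO between days 2 and 10 and in KO against WT at day 2, and epithelial and keratinocyte-like genes in KO against WT at day 2. A further pair of lists was made from the libraries themselves: ESC-high genes (at least 10 CPM in the ESC library and at least 8-fold over each of the 4 day 0 libraries) and pre-iPSC-high genes (the reverse).

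The genes named follow a rule: Kdm3b first, then for each comparison the 10 largest changes in each direction among called genes with a mean of at least 5 CPM and no overlap between the replicates compared (no such condition for interactions), leaving out unnamed transcripts, then up to 4 members per list with the lowest FDR and a mean of at least 1 CPM, and the members of the 2 lists reported by gene. Of these, the text names the ones needed to describe each group, and 1 gene is not reported here. The tests, lists, naming rule and most alternatives were chosen before the data were examined. The others, a block for days 0 and 2 only, a correction for transcript length, and fits with 1 replicate letter at days 0 and 2, were chosen after seeing the data.

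The fit was tested on data simulated for all pre-iPSC libraries from the mean of each group and the library sizes. WT at day 10 was given the means of WT at day 0, apart from 200 changed genes among 13379 tested. The fit called 5 of 67 genes changed 2-fold (7.46%), 53 of 67 changed 4-fold (79.1%) and 63 of 66 changed 8-fold (95.5%), 0 of them with the wrong sign, and 9 of 13179 unchanged genes. A raised list of 20 genes gave a camera p = 5.09e-62 (1.76e-06 with an estimated correlation), and of 200 random lists 2 fell under 0.05 (1 with an estimated correlation). Genes were simulated independently and without an effect of the replicate letter. These rates therefore do not cover the pairing of libraries at days 0 and 2 or correlation between genes.

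Replicate letters are shared between groups. Whether they pair the libraries was checked from the correlation of each library's deviation from its group mean: the 6 pairs of groups at days 0 and 2 correlated at 0.741 to 0.812, and the 9 pairs that involve day 10 at -0.061 to 0.049. The letters therefore pair the libraries at days 0 and 2 only, a pairing that comes from the data and not from the labels. Pearson correlations of log2 CPM within groups were 0.971 to 0.991.

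Alternatives were RLE factors, no count filter, the Wald test of DESeq2 1.42.0, only the libraries compared, the replicate block, a 2-fold minimum, each library left out in turn, other thresholds for the ESC-high lists, and the 4 added later. A gene at 0 counts in a group was given a lower bound of its fold change against 3 counts over that group, and a gene with 1 to 3 counts a ratio with a 95% counting interval. Both use counts pooled over each group, so they can differ slightly from ratios of mean CPM. Intervals and floors cover counting error only. The p-values measure only the spread between these libraries. Exon-level reads, noncoding genes and genome coordinates are not analysed here.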

Results

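Expression was measured by single-end RNA sequencing in mouse pre-iPSCs, cells made from embryonic fibroblasts that stalled during reprogramming to pluripotency. Wild-type (WT) cells and cells with a knockout (KO) of Kdm3b, which encodes an eraser of histone H3 lysine 9 methylation, were followed at day 0, day 2 and day 10 of treatment with ascorbic acid and a pair of kinase inhibitors, together called AA+2i. The inhibitors act on GSK3, which raises Wnt signalling, and on MEK, which lowers ERK signalling. Each of the 6 groups had 2 libraries, named replicates A and B, and 1 library came from embryonic stem cells (ESCs). The files cover 20325 genes, of which 14324 were tested in the 12 pre-iPSC libraries. In WT the totals were 26430050 (A) and 19261268 (B) expected counts at day 0, 20665010 and 20724006 at day 2, and 18144516 and 15460134 at day 10. In KO they were 22283033 and 20144526 at day 0, 20851653 and 14891294 at day 2, and 16005002 and 16512846 at day 10. The ESC library held 20083825. Values per group are mean library-size-normalised counts (CPM) ± SD with n = 2, and log2 fold changes carry their standard error (SE).

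Kdm3b itself was lower in KO at every time point. WT cells had 216 ± 53.3 CPM at day 0, 159 ± 19.003 at day 2 and 192 ± 0.0173 at day 10, against 54.7 ± 16.4, 24.1 ± 8.03 and 30.4 ± 15.0 CPM in KO, and the ESC library had 149 CPM. The log2 fold change of KO against WT was -1.98 at day 0 (SE 0.378, FDR = 0.0132), -2.71 at day 2 (SE 0.390, FDR = 0.00302) and -2.67 at day 10 (SE 0.389, FDR = 0.00121). A lower value at day 2 than at day 0 in KO was not called (log2 fold change -1.17, FDR = 0.121). The gene totals do not show which exons the remaining reads came from. The day 0 call was lost without WT day 0 B (log2 fold change -1.71) and without KO day 0 A (-1.71). With only the 4 libraries compared, the calls at day 0 (-1.96) and day 2 (-2.72) were both lost.

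The early response of WT cells was examined between day 0 and day 2. Some targets of Wnt signalling rose. Axin2, a feedback inhibitor of the pathway, rose from 0.368 ± 0.191 to 14.3 ± 3.53 CPM (log2 fold change 5.30, SE 0.538, FDR = 0.00167), and Tnfrsf19, another target, rose by a log2 fold change of 4.64. Sp5, a transcription factor downstream of Wnt, went from 3 counts to 270, a ratio of 96.6 with a 95% counting interval of 32.7 to 471. Some genes that report ERK activity fell. Dusp6, which encodes an ERK phosphatase, went from 90.5 ± 0.111 to 11.1 ± 0.0277 CPM (log2 fold change -3.03, SE 0.200, FDR = 0.000373). Dusp4 was at -2.82, the ETS factor Etv4 at -2.26 and the Ras inhibitor Spred1 at -1.69. Naive pluripotency factors were already rising, among them Tcfcp2l1 (the symbol in the files for Tfcp2l1), from 26.2 ± 8.81 to 267 ± 30.7 CPM, Klf2 (log2 fold change 2.86, SE 0.179) and Nanog, from 2.10 ± 1.05 to 15.9 ± 2.96 CPM.

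In all, 759 genes changed in WT by day 2 in edgeR's quasi-likelihood test, 476 higher and 283 lower. The count was 1433 with the replicate letter as a block (the replicate block) and 4318 with a block at days 0 and 2 only. It was 119 with only the 4 libraries compared, where Nanog, Krt19 and Gata2 lost their calls. Of 16 Wnt targets, 7 rose (10 adjusted over the list alone; camera adjusted p = 3.78e-10, and adjusted p = 0.144 with an estimated correlation), and of 19 ERK targets 8 fell (10 adjusted over the list alone; 9.12e-12, and adjusted p = 0.0605 with an estimated correlation). Of 18 epithelial genes 10 rose and 1 fell (12 and 1 adjusted over the list alone), at adjusted p = 1.02e-07 and adjusted p = 0.125 with an estimated correlation. The tight-junction gene Cldn4 rose by a log2 fold change of 4.58, while Krt19, a simple-epithelium keratin, fell by 1.62. Of 18 naive pluripotency genes 6 rose (7 higher and 3 lower adjusted over the list alone), at adjusted p = 0.000573 and adjusted p = 0.144 with an estimated correlation. Of 19 general pluripotency genes 5 rose and 1 fell (7 and 1 adjusted over the list alone), at adjusted p = 0.0146 and adjusted p = 0.338 with an estimated correlation. Trophectoderm markers, genes of the outer layer of the early embryo, rose in 4 of 13 cases and fell in 1 (10 and 1 adjusted over the list alone), at adjusted p = 1.86e-07 and adjusted p = 0.0605 with an estimated correlation. Hand1 and Gata2 were among them, with log2 fold changes of 3.07 and 2.59. Stress genes rose in 4 of 16 cases (6 higher and 1 lower adjusted over the list alone), at adjusted p = 0.00473 and adjusted p = 0.281 with an estimated correlation.

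Outside these lists, the signalling ligand Wnt8a rose from 2.45 ± 0.660 to 88.1 ± 26.5 CPM, the growth factor Mdk from 3.99 ± 0.194 to 95.8 ± 7.70 CPM, and the protease inhibitor Serpina3m by a log2 fold change of 5.54. The imprinted growth factor Igf2 rose by 2.89. The genes that fell most included Slc35d3, a solute carrier (-4.25), Tph1, an enzyme of serotonin synthesis (-4.09), and Vat1l (-3.59), and Mycn, a MYC family gene, fell by 1.90. The cell cycle list shifted down (adjusted p = 0.000292, and adjusted p = 0.575 with an estimated correlation) although 0 of its 22 members were called in edgeR, with 4 at an unadjusted p under 0.05 and 2 called by DESeq2. With fry the cell cycle call was lost (adjusted p = 0.227). Interferon response genes shifted up with 1 of 21 members called (2 adjusted over the list alone; adjusted p = 0.00595, and adjusted p = 0.156 with an estimated correlation). That call was lost without WT day 2 A (adjusted p = 0.0836). The count of 759 fell to 217 without WT day 0 A, 251 without WT day 2 A, 193 without WT day 0 B, 232 without WT day 2 B, 457 without WT day 10 A and 471 without WT day 10 B.

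By day 10 WT cells expressed the naive pluripotency network. Nanog rose from 2.10 ± 1.05 to 299.6 ± 25.2 CPM (log2 fold change 7.13, SE 0.387, FDR = 2.11e-05), and Esrrb, an orphan nuclear receptor of that network, from 0.460 ± 0.00994 to 401 ± 20.4 CPM (9.75, SE 0.623, FDR = 2.9e-05). Dppa5a, an RNA-binding protein of ESCs, reached 1996 ± 256 CPM from 11.7 ± 3.06, Tbx3 rose by a log2 fold change of 8.33, Dppa4 by 7.99 and Klf2 by 3.82. Germline genes that DNA methylation keeps silent in somatic cells were switched on. Dazl, which encodes an RNA-binding protein of germ cells, was at 0 counts in both day 0 libraries and at 202 ± 20.7 CPM at day 10, at least 3082-fold higher by pooled counts against a floor of 3 counts over the group. Antiviral genes followed, with Oasl2 rising from 0.0973 ± 0.138 to 104 ± 26.1 CPM and Isg15, a ubiquitin-like modifier, from 0.842 ± 0.0902 to 36.8 ± 0.654 CPM.

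In WT, 4889 genes differed between day 10 and day 0, 3012 higher and 1877 lower, and 9412 did with a block at days 0 and 2 only. All 19 tested germline genes rose (19 adjusted over the list alone; camera adjusted p = 5.02e-14). Tuba3a, a testis tubulin gene whose close copy makes its value uncertain, went from 1 count to 104 CPM, a ratio of 4793 (95% counting interval 860 to 189360). Stk31, a germ cell kinase gene, also started from 1 count (ratio 842, 151 to 33310). The meiotic synaptonemal gene Sycp1 and the helicase gene Ddx4 rose by log2 fold changes of 5.50 and 6.64. Of 21 interferon response genes 18 rose (18 adjusted over the list alone; adjusted p = 5.36e-09), including the transcription factor Irf7 (5.69). Of 13 trophectoderm markers 12 rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 4.16e-06), including the keratin gene Krt7 (8.08). Of 18 naive genes 13 rose and 1 fell (13 and 1 adjusted over the list alone), at adjusted p = 1.1e-05 and adjusted p = 0.0762 with an estimated correlation. Of 19 general pluripotency genes 13 rose and 1 fell (13 and 2 adjusted over the list alone), at adjusted p = 1.72e-05 and adjusted p = 0.0769 with an estimated correlation. Epithelial genes rose in 14 of 18 cases and fell in 1 (14 and 1 adjusted over the list alone), with Cldn4 at a log2 fold change of 5.91 and Krt8 at 4.04 (adjusted p = 1.04e-05, and adjusted p = 0.0959 with an estimated correlation).

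Among genes of the 2-cell embryo, 6 of 9 rose and 1 fell in WT (6 and 1 adjusted over the list alone; adjusted p = 0.0059, and adjusted p = 0.0762 with an estimated correlation). Zscan4f, a marker of that stage, had 0 counts at day 0 and 5.96 ± 0.162 CPM at day 10, at least 90.4-fold higher. ERK targets stayed down, with 11 of 19 lower (12 adjusted over the list alone; adjusted p = 2.92e-07, and adjusted p = 0.0762 with an estimated correlation). Etv4 fell from 115 ± 2.26 to 1.77 ± 0.134 CPM (log2 fold change -6.02, SE 0.196, FDR = 3.04e-06), Dusp6 by 4.19 and Dusp4 by 4.01. Of 16 Wnt targets 9 rose and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 0.0059, and adjusted p = 0.403 with an estimated correlation), with Axin2 at 4.79 and Tcf7, a Wnt effector, at 3.16. Stress genes rose in 7 of 16 cases and fell in 1 (7 and 1 adjusted over the list alone), with Trib3, a target of the amino acid response, at 2.13 (adjusted p = 0.0194, and adjusted p = 0.36 with an estimated correlation). Cell cycle genes fell in 4 of 22 cases (3 adjusted over the list alone; adjusted p = 0.0391, and adjusted p = 0.574 with an estimated correlation). That call was lost with fry (adjusted p = 0.146), and without WT day 0 A (0.169) or WT day 10 A (0.0969). The DNA methyltransferase gene Dnmt3b rose from 27.8 ± 3.85 to 69.1 ± 4.93 CPM and the cofactor gene Dnmt3l from 0 counts to 19.3 ± 1.77 CPM, at least 291-fold higher, while the DNA methylation list was not called (adjusted p = 0.463). Suv39h1, an H3K9 methyltransferase gene, fell by 1.76.

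Single mesenchymal and neural genes went down in WT by day 10, although neither list was called. Fibroblast and mesenchymal genes were higher in 9 of 27 cases and lower in 5 (12 and 6 adjusted over the list alone; adjusted p = 0.377), and neural markers higher in 3 of 12 and lower in 6 (3 and 6 adjusted over the list alone; 0.201). Vim, an intermediate filament gene, fell from 941 ± 61.2 to 265 ± 7.61 CPM, the N-cadherin gene Cdh2 by 4.85 on the log2 scale and the neural factor Sox11 by 3.28. The sialyltransferase gene St8sia2 was left with 2 counts over both day 10 libraries, a ratio of 0.00203 (95% counting interval 0.000246 to 0.00736). The cell adhesion gene Pecam1, expressed by both endothelium and naive ESCs, rose from 0.881 ± 0.0351 to 197 ± 12.7 CPM, and Igf2 rose by 4.31. The count of 4889 genes was 3000 without WT day 10 A and 3092 without WT day 10 B.

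**Figure D1:**
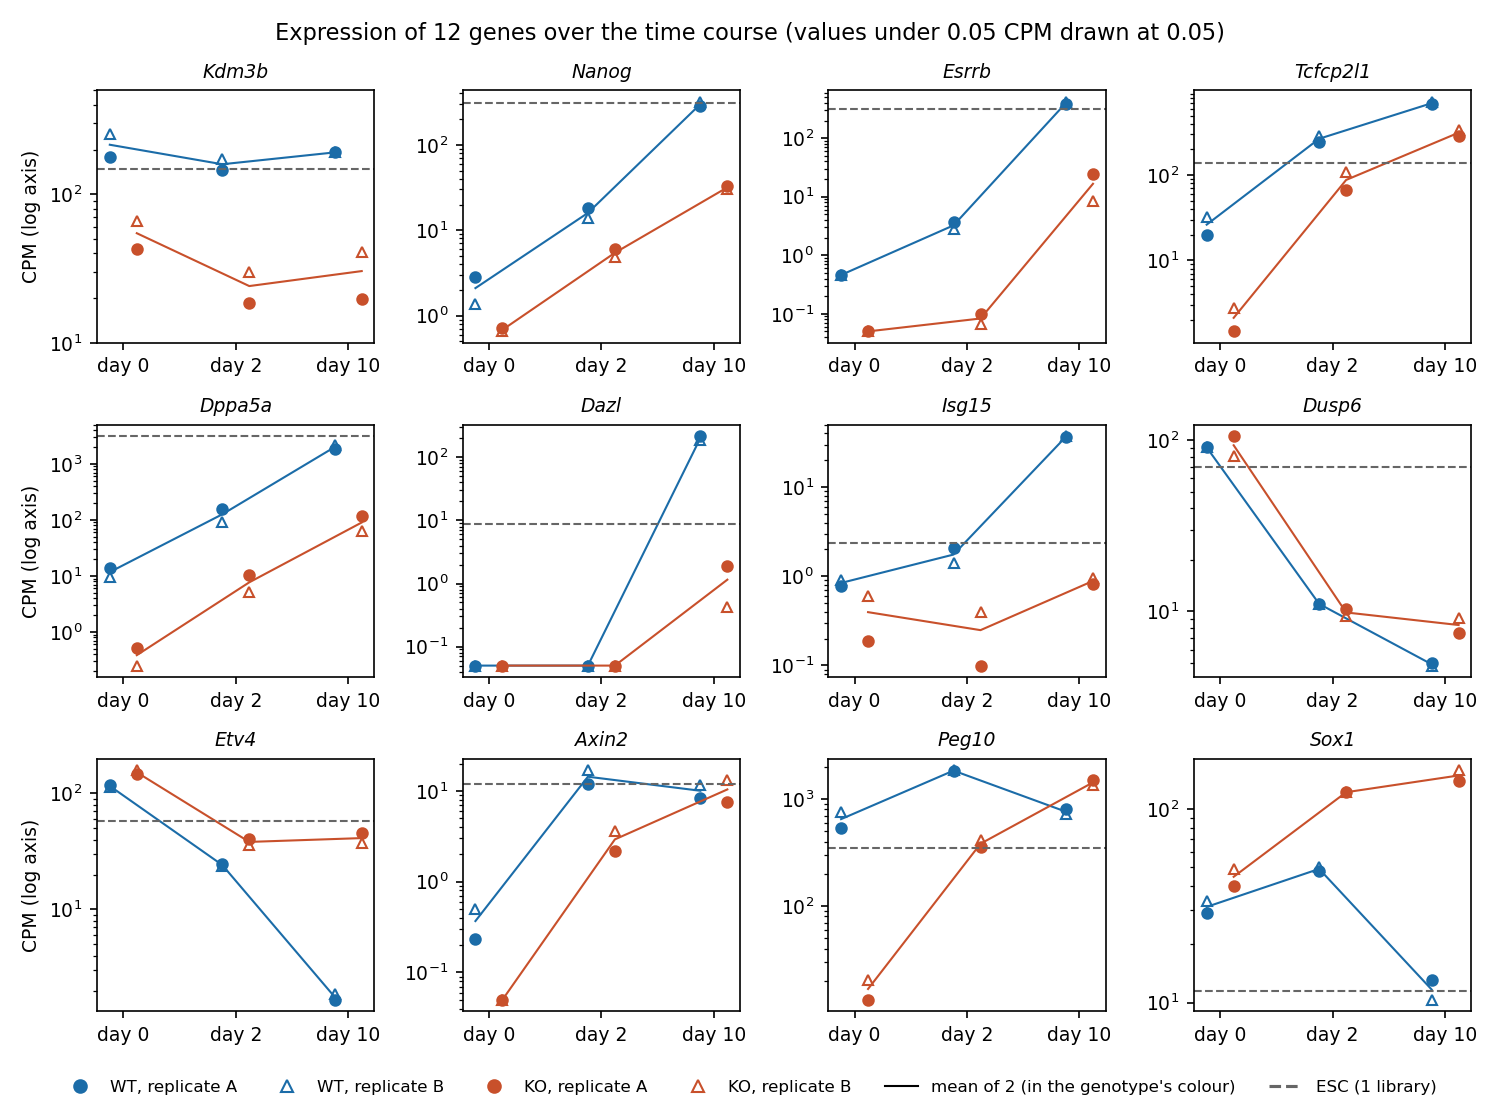
CPM (log axis) of 12 genes in each pre-iPSC library against day, with a line through the group means and a dashed line at the single ESC library. Nanog, Esrrb, Dazl and Isg15 were far higher in WT than in KO at day 10, Dusp6 fell in both, and Etv4 and Sox1 ended higher in KO.

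More WT genes changed after day 2 than before it: 4227 differed between day 10 and day 2, 2625 higher and 1602 lower, and 8984 did with a block at days 0 and 2 only. The replicate letters paired the libraries of days 0 and 2 but not those of day 10, and no untreated cells were sampled at day 10. Wherever day 10 is compared with an earlier day, a difference between sets of libraries cannot be told apart from the treatment. Germline genes rose as a list between these days (19 of 19 members, and 19 adjusted over the list alone; adjusted p = 9.57e-16), as did interferon response genes (17 of 21, and 18 adjusted over the list alone; 3.52e-08). Naive (12 of 18 higher, 1 lower, and 12 and 1 adjusted over the list alone; adjusted p = 3.05e-05, and adjusted p = 0.0811 with an estimated correlation) and general pluripotency genes (14 of 19 higher, and 14 adjusted over the list alone; 2.28e-05, and adjusted p = 0.0811 with an estimated correlation) rose further. Genes of the 2-cell stage (6 of 9 higher, and 6 adjusted over the list alone; adjusted p = 0.00202, and adjusted p = 0.0811 with an estimated correlation), trophectoderm markers (6 of 13 higher, and 7 adjusted over the list alone; 0.00139, and adjusted p = 0.0811 with an estimated correlation) and primitive endoderm markers (5 of 12 higher, and 5 adjusted over the list alone; 0.00828, and adjusted p = 0.345 with an estimated correlation) rose too. Epithelial genes rose in 8 of 18 cases and fell in 1 (10 and 2 adjusted over the list alone; adjusted p = 0.00391, and adjusted p = 0.338 with an estimated correlation), while ERK targets fell in 6 of 19 and rose in 1 (6 and 1 adjusted over the list alone; 0.00521, and adjusted p = 0.338 with an estimated correlation). The count was 2643 without WT day 2 A, 2311 without WT day 10 A, 2506 without WT day 2 B and 2304 without WT day 10 B.

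KO cells answered the first 2 days of treatment with many of the same changes. Tcfcp2l1 rose from 2.12 ± 0.918 to 87.7 ± 28.4 CPM (log2 fold change 5.39, SE 0.398, FDR = 0.000222), Klf2 from 1.68 ± 0.0314 to 19.8 ± 2.87 CPM and Nanog from 0.682 ± 0.0397 to 5.44 ± 0.838 CPM. Axin2 went from 1 count in the day 0 group to 2.92 ± 1.03 CPM, a ratio of 116 (95% counting interval 20.3 to 4613). Dusp6 fell from 93.2 ± 17.1 to 9.87 ± 0.631 CPM, Dusp4 by 2.96 and Etv4 by 1.97. Peg10, an imprinted gene derived from a retrotransposon, rose from 16.8 ± 4.92 to 381 ± 39.7 CPM (log2 fold change 4.52, SE 0.314), and the neural factor Sox1 from 44.7 ± 6.33 to 122 ± 0.456 CPM.

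In KO, 915 genes changed by day 2, 576 higher and 339 lower. The count was 1478 with the replicate block and 4225 with a block at days 0 and 2 only. Of 19 ERK targets 9 fell (13 adjusted over the list alone), at camera adjusted p = 3.86e-12 and adjusted p = 0.112 with an estimated correlation. Of 18 epithelial genes 5 rose and 1 fell (7 and 1 adjusted over the list alone), with Cldn4 at a log2 fold change of 5.35 and Epcam at 2.36 (adjusted p = 0.0064, and adjusted p = 0.5 with an estimated correlation). Of 18 naive genes 4 rose and 3 fell (6 and 4 adjusted over the list alone; adjusted p = 0.0402, adjusted p = 0.5 with an estimated correlation and 0.0706 with the replicate block). That call was also lost without WT day 10 A (0.0506), KO day 2 A (0.164) or KO day 0 B (0.181). Neural markers rose in 3 of 12 cases (3 adjusted over the list alone), with the microtubule gene Mtap2 (Map2) at 3.01 (adjusted p = 0.0381, adjusted p = 0.295 with an estimated correlation and 0.0637 with the replicate block; 0.113 without KO day 2 A and 0.181 without KO day 0 B). Cholesterol synthesis genes shifted down with 1 of 19 called (1 adjusted over the list alone), and Insig1, a sterol sensor gene, fell by 1.01 (adjusted p = 0.0064, and adjusted p = 0.295 with an estimated correlation; 0.113 without KO day 2 A and 0.0612 without KO day 0 B). The cell cycle list shifted down (adjusted p = 0.00586, and adjusted p = 0.697 with an estimated correlation; 0.335 without KO day 0 A and 0.255 without KO day 2 B) with 0 of 22 members called in edgeR, 2 at an unadjusted p under 0.05 and 1 called by DESeq2. With fry the cell cycle call was lost (adjusted p = 0.217). Some lists that camera called in WT by day 2 were not called in KO. They were general pluripotency (adjusted p = 0.0507), stress (0.0507), Wnt (0.0738), interferon response (0.435) and trophectoderm genes (0.479). Wnt8a (log2 fold change 7.01), the chaperone gene Ric3 (6.49), the zinc finger gene Sp8 (4.54) and Trib3 (2.00) rose, while the calcium-binding protein gene S100a4 (-5.52) and the receptor gene Calcrl (-5.18) fell. The count of 915 was 456 without KO day 0 A, 453 without KO day 0 B and 472 without KO day 2 B. With only the 4 libraries compared, edgeR called 0 genes, with 1199 at an unadjusted p under 0.05, and DESeq2 1541 in all 12.

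By day 10 KO cells had switched on naive factors, though to lower levels than WT for most of them. Klf2 rose from 1.68 ± 0.0314 to 54.3 ± 5.51 CPM (SE of the log2 fold change 0.204, FDR = 8.55e-06), Tcfcp2l1 from 2.12 ± 0.918 to 314 ± 38.9 CPM and Nanog from 0.682 ± 0.0397 to 31.7 ± 1.56 CPM. Esrrb went from 1 count in the group to 16.6 ± 11.7 CPM, a ratio of 674 (95% counting interval 121 to 26689), and Dppa5a reached 90.0 ± 36.8 CPM. Peg10 climbed to 1426 ± 117 CPM, and Dusp6 (log2 fold change -3.49) and Etv4 (-1.89) stayed down.

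In KO, 2165 genes differed between day 10 and day 0, 1422 higher and 743 lower. The count was 3284 with the replicate block and 6840 with a block at days 0 and 2 only. Of 18 naive genes 13 rose and 1 fell (13 and 2 adjusted over the list alone; camera adjusted p = 5.21e-07, and adjusted p = 0.0594 with an estimated correlation). Of 19 general pluripotency genes 11 rose and 1 fell (13 and 1 adjusted over the list alone), with the NODAL coreceptor gene Tdgf1 at a log2 fold change of 4.27 and Gdf3 at 4.85 (adjusted p = 8.86e-06, and adjusted p = 0.108 with an estimated correlation). Epithelial genes rose in 11 of 18 cases (13 higher and 2 lower adjusted over the list alone), with Cldn4 at 8.38 and Epcam at 2.60 (adjusted p = 1.65e-06, and adjusted p = 0.108 with an estimated correlation). Trophectoderm markers rose in 7 of 13 cases (10 higher and 1 lower adjusted over the list alone; adjusted p = 5.21e-07, and adjusted p = 0.0594 with an estimated correlation). Hand1 went from 0 counts to 2.23 ± 0.0302 CPM, at least 30.6-fold higher, and Gata2 rose by 3.41. Of 16 Wnt targets 7 rose (8 adjusted over the list alone; adjusted p = 0.00124, and adjusted p = 0.417 with an estimated correlation), Axin2 from 1 count by a ratio of 428 (95% counting interval 76.4 to 16966). Of 19 ERK targets 8 fell (8 adjusted over the list alone), at adjusted p = 4.63e-05 and adjusted p = 0.139 with an estimated correlation.

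Only 4 of 19 germline genes rose in KO by day 10 (4 adjusted over the list alone; adjusted p = 0.0313, and adjusted p = 0.355 with an estimated correlation). The list's call was lost without KO day 2 A (0.0585), KO day 0 B (0.156) or KO day 2 B (0.0636). Of 21 interferon response genes 5 rose (5 adjusted over the list alone), with Irf7 at a log2 fold change of 2.54 (adjusted p = 0.00522, and adjusted p = 0.139 with an estimated correlation). Cholesterol synthesis genes went the other way, with 6 of 19 lower (6 adjusted over the list alone; adjusted p = 1.23e-05, and adjusted p = 0.0594 with an estimated correlation) and Insig1 at -1.10. Mtap2 (3.32), Sox1 (1.73), Sp8 (5.02) and Wnt8a (7.66) stayed up, and Calcrl (-6.03) and the myogenic factor Pax7 (-5.60) fell. The cell cycle list shifted down with 1 of 22 called (1 adjusted over the list alone; adjusted p = 0.024, and adjusted p = 0.649 with an estimated correlation; 0.461 without KO day 0 A and 0.0777 without KO day 10 B). With fry the cell cycle call was lost (adjusted p = 0.281). The count of 2165 was 1290 without KO day 0 A, 1005 without KO day 10 A, 1230 without KO day 0 B and 1131 without KO day 10 B.

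Between day 2 and day 10, 444 genes changed in KO, of which 357 were higher and 87 lower. The higher genes were 80.4% of those called, and 66.8% of the 1341 that DESeq2 called. Their share was 61.3% of the 1152 called with the replicate block and 50.8% of the 5328 with a block at days 0 and 2 only. They were 58.7% of 3282 with replicate A alone at days 0 and 2 and 50.8% of 6667 with replicate B alone, fits in which each group of those days is a single library and the spread comes from the day 10 replicates. Naive genes rose in 10 of 18 cases (15 adjusted over the list alone; camera adjusted p = 1.2e-11) and trophectoderm markers in 5 of 13 (9 adjusted over the list alone; 2.4e-11). General pluripotency genes rose in 8 of 19 cases and fell in 1 (10 and 1 adjusted over the list alone; adjusted p = 1.02e-05, and adjusted p = 0.103 with an estimated correlation). Epithelial genes rose in 4 of 18 cases (11 adjusted over the list alone; 1.13e-06, and adjusted p = 0.103 with an estimated correlation). Keratinocyte-like markers (1 of 11 higher, and 5 adjusted over the list alone; adjusted p = 0.00213, and adjusted p = 0.103 with an estimated correlation), interferon response genes (2 of 21 higher, and 4 adjusted over the list alone; 0.0228, and adjusted p = 0.228 with an estimated correlation; 0.125 without KO day 2 A and 0.0565 without KO day 10 B) and endothelial markers (3 of 10 higher, and 5 higher and 2 lower adjusted over the list alone; 0.036, and adjusted p = 0.425 with an estimated correlation; 0.29 without KO day 2 A) shifted up. In edgeR 0 germline genes were called (4 adjusted over the list alone), with 5 at an unadjusted p under 0.05 and 2 called by DESeq2, and the list shifted up (adjusted p = 0.0113, and adjusted p = 0.233 with an estimated correlation; 0.0901 without KO day 2 A). Wnt targets also had 0 members called (3 adjusted over the list alone), with 6 at an unadjusted p under 0.05 and 3 called by DESeq2 (shifted up, adjusted p = 0.00155, and adjusted p = 0.391 with an estimated correlation; 0.125 without KO day 2 A). With fry the Wnt call was lost (adjusted p = 0.0658). Cholesterol synthesis genes had 0 called (2 adjusted over the list alone), with 4 at an unadjusted p under 0.05 and 2 by DESeq2 (shifted down, adjusted p = 0.00569, and adjusted p = 0.152 with an estimated correlation; 0.0714 without KO day 10 B). The count of 444 was 268 without WT day 2 A, 211 without WT day 10 A, 264 without WT day 2 B, 222 without WT day 10 B, 149 without KO day 2 A, 113 without KO day 10 A, 112 without KO day 2 B and 192 without KO day 10 B. With only the 4 libraries compared edgeR called 0, with 1382 at an unadjusted p under 0.05.

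**Figure D2:**
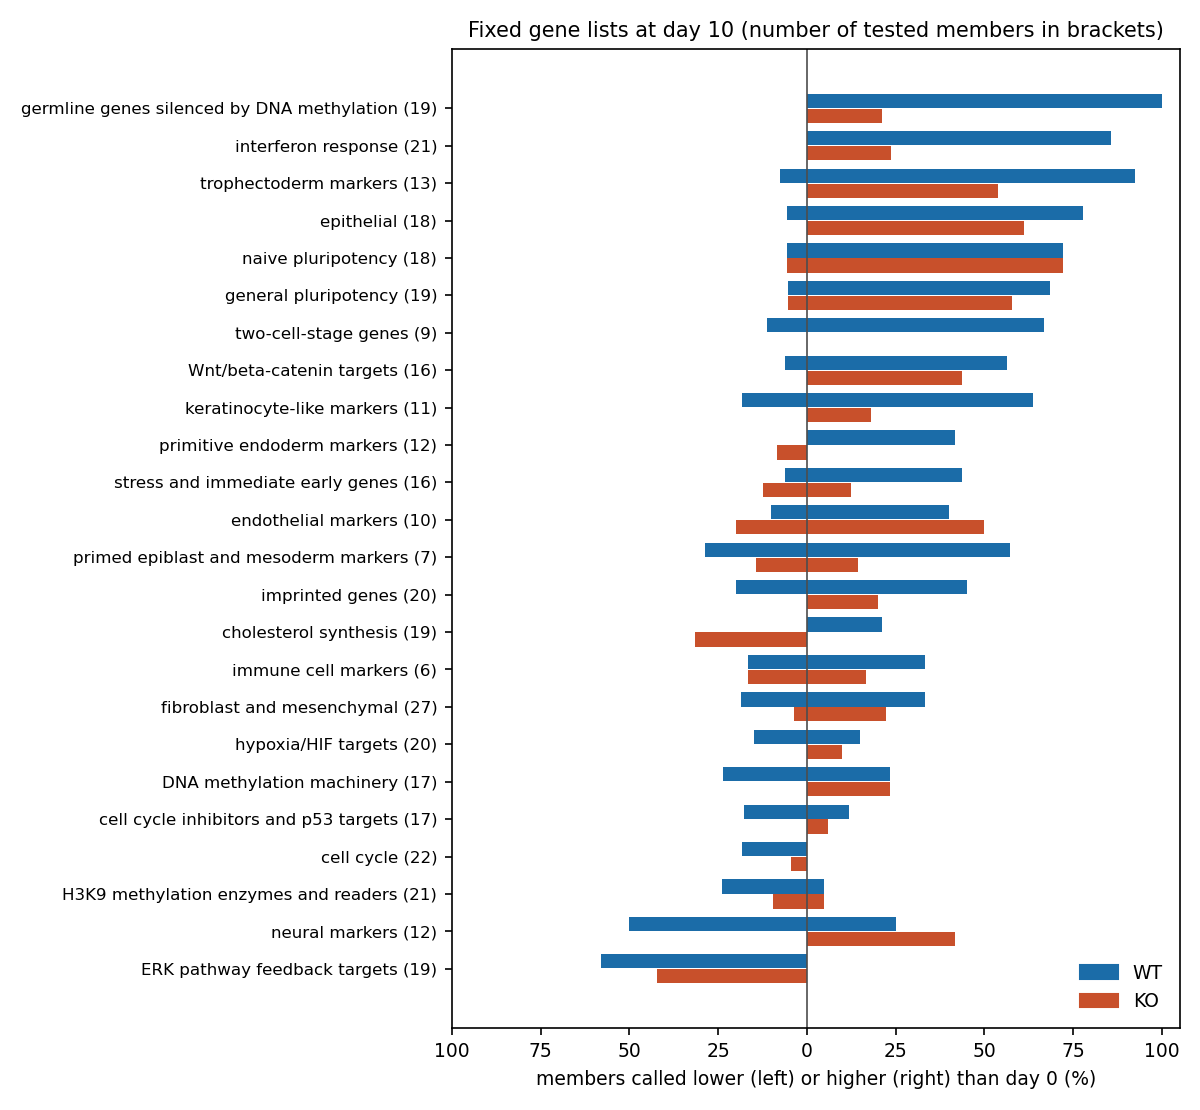
Share of the tested members of each fixed list (%) that edgeR called lower (bars to the left) or higher (bars to the right) at day 10 than at day 0, in WT and in KO. All 19 germline genes and 18 of 21 interferon response genes rose in WT, against 4 and 5 in KO, while 13 of 18 naive genes rose in both.

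KO and WT cells were compared at each day, and they already differed at day 0. The labels do not say how many cell lines stand behind each genotype, so a difference between lines cannot be told apart from the knockout. Tdgf1 was at 3.92 ± 0.280 CPM in KO against 130 ± 24.2 in WT (log2 fold change -5.05, SE 0.335, FDR = 9.99e-05). Peg10 was at 16.8 ± 4.92 CPM against 648 ± 154, and the proteoglycan gene Srgn at 0.710 ± 0.134 CPM against 92.5 ± 11.5. Gsta1, a detoxification enzyme gene, had 0 counts in both KO libraries against 13.3 ± 1.06 CPM in WT, at least 184-fold lower by pooled counts. Gpr37, a receptor gene, was higher in KO, at 71.7 ± 24.2 CPM against 2.30 ± 0.664.

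At day 0, 1187 genes differed between genotypes, 386 higher and 801 lower in KO, and 1792 did with the replicate block (707 higher and 1085 lower). The split was near even with a block at days 0 and 2 only (2150 higher and 2210 lower), and with replicate B alone, a single library per group with no replicate at day 0, it was 1298 higher and 1162 lower. With only the 4 libraries compared, 141 genes were called, 19 higher and 122 lower, and Epcam, Krt19, Mest, Insig1 and Dnmt3b lost their calls. Of 19 general pluripotency genes 8 were lower (11 adjusted over the list alone; adjusted p = 6.2e-07, and adjusted p = 0.0864 with an estimated correlation). Of 18 naive genes 5 were lower (12 lower and 1 higher adjusted over the list alone), among them Tcfcp2l1 (log2 fold change -3.63), Klf2 (-2.47) and Klf5 (-2.43), at adjusted p = 7.17e-05 and adjusted p = 0.087 with an estimated correlation. Of 18 epithelial genes 8 were lower (10 adjusted over the list alone), including Krt8 (-3.71), Epcam (-2.36) and Krt19 (-2.18), at adjusted p = 1.75e-07 and adjusted p = 0.087 with an estimated correlation. Keratinocyte-like markers were lower in 6 of 11 cases (7 lower and 1 higher adjusted over the list alone; adjusted p = 6.68e-06, and adjusted p = 0.0691 with an estimated correlation), with the stratifin gene Sfn at -3.78. Trophectoderm (6 of 13 lower, 6 adjusted over the list alone; 0.00206, and adjusted p = 0.0938 with an estimated correlation) and fibroblast genes (6 of 27 lower and 2 higher, and 9 and 2 adjusted over the list alone; 0.00161, and adjusted p = 0.386 with an estimated correlation) were lower too. Cholesterol synthesis genes were higher in KO in 4 of 19 cases (8 adjusted over the list alone), with Insig1 at 197 ± 2.76 CPM against 77.8 ± 2.78 (adjusted p = 5.38e-06, and adjusted p = 0.0691 with an estimated correlation). Interferon response genes were lower in 4 of 21 cases (5 adjusted over the list alone; 0.00998, and adjusted p = 0.16 with an estimated correlation; 0.0531 without KO day 0 A). Stress genes were higher in 3 of 16 cases and lower in 1 (6 and 2 adjusted over the list alone), with Chac1, a glutathione-degrading enzyme gene, at 2.84 (adjusted p = 0.0173, and adjusted p = 0.379 with an estimated correlation; 0.0676 without WT day 0 B and 0.125 without KO day 0 A). Mtap2 (-3.61), the imprinted gene Mest (-2.12) and Dnmt3b (-1.71) were lower in KO, and the POU factor gene Pou3f1 was higher (2.88). The count was 626 without WT day 0 A, 547 without WT day 0 B, 636 without KO day 0 A and 571 without KO day 0 B.

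At day 2 most of these lists were lower in KO again, while fibroblast genes were not called as a list (adjusted p = 0.0501). Krt8 was at 0.706 ± 0.0593 CPM in KO against 21.1 ± 1.24 in WT (log2 fold change -4.87, SE 0.406, FDR = 0.000283), and Gata2 at 0.498 ± 0.140 CPM against 16.7 ± 5.10. Dppa5a was at 7.69 ± 3.65 CPM against 126 ± 46.5, and Klf2 at 19.8 ± 2.87 against 67.7 ± 1.92. Peg10 had narrowed its gap, at 381 ± 39.7 CPM against 1838 ± 14.0. Gpr37 stayed higher in KO (3.69), joined by Ric3 at 118 ± 62.2 CPM against 7.59 ± 3.46.

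At day 2, 1498 genes differed, 615 higher and 883 lower in KO, and 2293 did with the replicate block (1049 higher and 1244 lower). The split turned with a block at days 0 and 2 only (2699 higher and 2553 lower) and was 1703 and 1641 with replicate B alone, a single library per group. With only the 4 libraries compared, 79 genes were called, 8 higher and 71 lower, and Klf2, Tdh, Dppa5a, Cldn4, Rhox9, Oas1a, Igf2, Peg10, Dnmt3b, Sp8, Ric3, Vldlr and Antxr1 lost their calls. Of 18 epithelial genes 12 were lower (12 adjusted over the list alone; adjusted p = 1.52e-10, and 0.0493 with an estimated correlation), including Cldn4 (-3.84). Of 18 naive genes 10 were lower (12 lower and 1 higher adjusted over the list alone; 1.14e-06), including the metabolic gene Tdh (-1.36). Of 13 trophectoderm markers 7 were lower (9 adjusted over the list alone; 3.43e-10), including the homeobox gene Rhox9 (-6.40). Of 11 keratinocyte-like markers 6 were lower (9 lower and 1 higher adjusted over the list alone; 4.81e-07), including Sfn (-3.17). Of 19 general pluripotency genes 8 were lower and 1 higher (12 and 2 adjusted over the list alone), with Tdgf1 at -3.15 (adjusted p = 6.15e-06, and adjusted p = 0.0752 with an estimated correlation). Interferon response genes were lower in 5 of 21 cases (6 adjusted over the list alone), with Oas1a, an RNA sensor gene, at -3.51 (adjusted p = 0.000605, and adjusted p = 0.0752 with an estimated correlation). Wnt targets were lower in 5 of 16 cases and higher in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.000605, and adjusted p = 0.395 with an estimated correlation; 0.0626 without KO day 2 A). Cholesterol synthesis genes were higher in 2 of 19 cases (5 adjusted over the list alone; 0.00378, and adjusted p = 0.119 with an estimated correlation). Igf2 (-2.47) and Dnmt3b (-1.93) were lower, and Sp8 (2.95), the lipoprotein receptor gene Vldlr (3.82) and the collagen receptor gene Antxr1 (4.07) were higher. The count was 760 without WT day 2 A, 647 without WT day 2 B and 889 without KO day 2 B.

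At day 10 the genotypes were far apart. Nanog was at 31.7 ± 1.56 CPM in KO against 299.6 ± 25.2 in WT (log2 fold change -3.25, SE 0.318, FDR = 0.000198), and Tdgf1 at 76.3 ± 27.8 CPM against 599.7 ± 54.0. Dazl was at 1.15 ± 1.03 CPM in KO against 202 ± 20.7 (FDR = 0.0017), a call that DESeq2 did not make. Oasl2 was at 1.45 ± 0.524 CPM against 104 ± 26.1, and Isg15 at 0.886 ± 0.101 against 36.8 ± 0.654. Some genes that fell in WT were higher in KO. Etv4, which fell less in KO, was at 41.1 ± 5.73 CPM against 1.77 ± 0.134, Vim at 1061 ± 30.5 against 265 ± 7.61, and Sox1, which rose in KO, at 149 ± 13.2 against 11.7 ± 1.91.

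At day 10, 4628 genes differed, 1782 higher and 2846 lower in KO, and 9136 did with a block at days 0 and 2 only. Germline genes were lower in 18 of 19 cases (19 adjusted over the list alone; adjusted p = 5.24e-13), including Ddx4 (log2 fold change -5.74), Stk31 (-5.53) and Sycp1 (-4.80). The meiotic cohesin gene Rec8, outside the list, was at -7.22. Interferon response genes were lower in 18 of 21 cases (19 adjusted over the list alone; 1.55e-09), including Irf7 (-3.56). Of 19 general pluripotency genes 15 were lower (15 lower and 1 higher adjusted over the list alone), among them Dppa4 (-4.71), at adjusted p = 8.36e-06 and adjusted p = 0.0822 with an estimated correlation. Of 18 naive genes 13 were lower and 2 higher (13 and 2 adjusted over the list alone; 0.000786, and adjusted p = 0.111 with an estimated correlation), with Fgf4 at -2.39 and Tcl1, a kinase coactivator gene of ESCs, at -5.38. Epithelial genes were lower in 14 of 18 cases (14 lower and 1 higher adjusted over the list alone), with Krt8 at -4.03 and Cldn7 at -3.62 (adjusted p = 1.21e-05, and adjusted p = 0.111 with an estimated correlation). Trophectoderm markers (10 of 13 lower, 11 adjusted over the list alone; adjusted p = 0.000148, and adjusted p = 0.0629 with an estimated correlation) included Krt7 (-5.39). Genes of the 2-cell stage were lower in 6 of 9 cases (6 adjusted over the list alone; 0.000861, and adjusted p = 0.0629 with an estimated correlation). Keratinocyte-like markers were lower in 8 of 11 cases and higher in 2 (8 and 2 adjusted over the list alone; 0.0189, and adjusted p = 0.154 with an estimated correlation). ERK targets were the main list that was higher, in 10 of 19 cases with 1 lower (10 and 1 adjusted over the list alone; 0.00154, and adjusted p = 0.204 with an estimated correlation), including Etv1 (2.00) and Dusp4 (1.76).

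A pair of smaller list differences at day 10 rested on single libraries. Cell cycle inhibitors and p53 targets were higher in KO in 4 of 17 cases and lower in 1 (5 and 1 adjusted over the list alone; adjusted p = 0.0415, and adjusted p = 0.363 with an estimated correlation; 0.0806 without WT day 10 B and 0.0564 without KO day 10 A). Primitive endoderm markers were lower in 5 of 12 cases (6 adjusted over the list alone; 0.0475, adjusted p = 0.381 with an estimated correlation and 0.0621 with the replicate block). That call was also lost with RLE factors (0.0547), and without WT day 10 A (0.106), KO day 10 A (0.0538), KO day 0 B (0.0515), KO day 2 B (0.0534) or KO day 10 B (0.0622). Foxd1, a forkhead factor gene, was at 280.1 ± 45.0 CPM in KO against 10.7 ± 0.457 in WT. Cdh2 was higher by 4.14, the repressor gene Zeb2 by 3.36, Sox11 by 2.20, Sp8 by 5.13 and Suv39h1 by 1.28. These are single genes: neither the fibroblast nor the neural list was called for KO against WT at day 10. The collagen gene Col1a1 (-7.92) and Pecam1 (-5.49) were lower in KO, as were Igf2 (-2.09), Dnmt3b (-2.13) and the dioxygenase gene Tet1, whose enzyme uses ascorbic acid (-2.07). Trib3 (-2.31) and the asparagine synthetase gene Asns (-2.38) were also lower. The count of 4628 was 2676 without WT day 10 A, 2669 without WT day 10 B, 2849 without KO day 10 A and 2620 without KO day 10 B.

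Whether the 2 genotypes responded differently was tested directly as an interaction. At day 2, 28 genes differed in edgeR, 18 with a more positive and 10 with a more negative log2 change in KO, with 996 at an unadjusted p under 0.05, 223 in DESeq2 and 91 with the replicate block. The count rose to 1109 with a block at days 0 and 2 only (692 more positive and 417 more negative), 122 with replicate A alone at days 0 and 2 and 128 with replicate B alone. Peg10 rose more in KO (interaction log2 3.02, SE 0.392, FDR = 0.029) and Igf2 less (-3.43, FDR = 0.0113). Trophectoderm markers rose less in KO as a list (1 of 13 called and 2 adjusted over the list alone; camera adjusted p = 3.8e-08, and 0.0434 with an estimated correlation). Neural markers shifted up (1 of 12 called and 3 adjusted over the list alone; adjusted p = 0.00388, and adjusted p = 0.152 with an estimated correlation; 0.133 without KO day 0 B). Wnt targets rose less in KO (9.52e-06, and adjusted p = 0.476 with an estimated correlation) with 0 of 16 called in edgeR (3 adjusted over the list alone), 4 at an unadjusted p under 0.05 and 3 in DESeq2. Epithelial genes rose less as a list (0.00424, and adjusted p = 0.476 with an estimated correlation; 0.264 without KO day 2 A and 0.137 without KO day 0 B) with 0 of 18 called (1 adjusted over the list alone), 1 at an unadjusted p under 0.05 and 1 in DESeq2. With fry, the calls of Wnt targets (adjusted p = 0.172) and epithelial genes (0.46) were lost. The count of 28 became 0 with only the libraries compared (708 at an unadjusted p under 0.05), and without WT day 0 A (863 at an unadjusted p under 0.05), WT day 2 A (746), WT day 0 B (784) or KO day 0 B (976). It was 2, both with a more negative change, without WT day 2 B or KO day 0 A, 9 without WT day 10 A or WT day 10 B, 14 without KO day 2 A, 12 without KO day 10 A or KO day 10 B and 10 without KO day 2 B. Leaving out any 1 of the 12 libraries ended the Peg10 call (adjusted p from 0.0601 without KO day 2 A to 0.206 without WT day 2 B). Igf2 lost its call without WT day 0 A (0.0767), WT day 2 A (0.0583), WT day 0 B (0.0604), WT day 2 B (0.0667) or KO day 0 B (0.0698).

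At day 10 the responses differed for 1798 genes, 910 with a more positive and 888 with a more negative log2 change in KO. The count was 2746 in DESeq2 (1284 and 1462), 2942 with the replicate block (1509 and 1433) and 6388 with a block at days 0 and 2 only (3419 and 2969). Germline genes rose less in KO (5 of 19 called and 5 adjusted over the list alone; camera adjusted p = 2.77e-16), as did interferon response genes (4 of 21 called and 7 adjusted over the list alone; 3.8e-07). Dppa4 (interaction log2 -6.07, SE 0.740), Fgf4 (-2.67), Igf2 (-3.05), Asns (-3.27) and Trib3 (-2.99) rose less or fell more in KO. Peg10 (6.16), Wnt8a (7.83), Mtap2 (3.48), Sox1 (3.14) and Zeb2 (2.56) had the more positive change in KO, and Etv4 fell less there (4.13). Peg10 and Mtap2 had started lower in KO at day 0 (log2 fold changes -5.27 and -3.61). For them a more positive change need not mean a higher level at day 10. ERK targets fell less in KO (5 of 19 called with 1 the other way, and 9 and 1 adjusted over the list alone; 0.000564, and adjusted p = 0.226 with an estimated correlation). Cholesterol synthesis genes fell in KO against WT (5 of 19 called and 9 adjusted over the list alone), with Insig1 at -1.92 (0.0011, and adjusted p = 0.126 with an estimated correlation). Genes of the 2-cell stage rose less (1 of 9 called and 1 adjusted over the list alone; 0.00104, and adjusted p = 0.0636 with an estimated correlation). Primitive endoderm markers rose less (3 of 12 called and 3 adjusted over the list alone; 0.0314, and adjusted p = 0.493 with an estimated correlation; 0.073 without WT day 0 A, 0.0733 without WT day 10 A and 0.0977 without KO day 0 B). Neural markers shifted up (4 of 12 called with 2 the other way, and 4 and 2 adjusted over the list alone; 0.0394, adjusted p = 0.21 with an estimated correlation and 0.0685 with the replicate block). That call was lost without WT day 2 A (0.051), WT day 2 B (0.0512), KO day 2 A (0.0514), KO day 0 B (0.111), KO day 2 B (0.0508) or KO day 10 B (0.0711). Naive pluripotency genes split, 7 with a more positive and 5 with a more negative log2 change in KO (adjusted p = 0.308). The count was 1143 without WT day 0 A, 925 without WT day 10 A, 1192 without WT day 0 B, 935 without WT day 10 B, 1014 without KO day 10 A, 1129 without KO day 0 B and 972 without KO day 10 B.

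The responses of the genotypes, each measured against its own day 0, overlapped. At day 2, 229 genes were higher in both (19.14 for independent lists) and 135 lower in both (6.70). At day 10, 790 were higher in both (299 for independent lists) and 366 lower in both (97.4). Both day 10 comparisons span the same change in how the libraries paired, so a library difference could add to this overlap. The genes that rose in WT by day 10 had a median log2 fold change of 2.65 in WT and 0.77 in KO, and the KO change had the same sign for 73.5% of them. Choosing genes by a call in WT favours the larger value there: the genes that rose in KO had medians of 2.32 in KO and 1.18 in WT. The interaction test found a smaller change in KO for 786 of the 3012 genes that rose in WT and a larger one for 76. The genes that fell in WT had medians of -1.22 in WT and -0.31 in KO, with 570 of 1877 changing less in KO. Those that fell in KO had medians of -1.25 in KO and -0.69 in WT. The interaction uses the WT change by which the 3012 and 1877 genes were chosen. That choice therefore also favours the counts of smaller changes in KO. The 229 became 93 without WT day 0 A, 123 without WT day 2 A, 89 without WT day 0 B, 108 without WT day 2 B and 134 without KO day 0 A. The 135 became 51, 31, 39 and 33 without the same WT libraries, 78 and 85 without WT day 10 A and WT day 10 B, 82 without KO day 2 A, 74 without KO day 0 B and 79 without KO day 2 B. The 790 became 504 without WT day 10 A, 464 without KO day 0 A and 448 without KO day 10 A. The 366 became 172 without WT day 10 A, 228 without WT day 0 B, 243 without WT day 2 B, 193 without WT day 10 B, 114 without KO day 10 A, 157 without KO day 0 B and 126 without KO day 10 B.

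How far each genotype moved towards ESCs was measured on 397 ESC-high genes, at least 8-fold higher in the ESC library than in each day 0 library, and on 164 pre-iPSC-high genes, at least 8-fold lower. WT cells at day 10 had covered 75.7% ± 1.01 (SD, n = 2) of the mean log2 distance of the ESC-high genes and KO cells 25.5% ± 6.64. The SDs of these shares cover the day 10 libraries only, with the day 0 mean and the ESC library held fixed. At day 2 the means were 11.7% in WT and 8.58% in KO. Of the pre-iPSC-high distance, WT cells at day 10 had covered 40.0% ± 2.74 and KO cells 12.4% ± 2.05, or 5.63% with a list chosen on WT at day 0. In WT at day 10, 360 ESC-high genes rose and 3 fell, and 138 pre-iPSC-high genes fell. In KO 169 ESC-high genes rose and 2 fell, and 47 pre-iPSC-high genes fell while 13 rose. KO was lower than WT at day 10 for 356 ESC-high genes and higher for 4, and the interaction was negative for 122 and positive for 12. These lists were chosen on the same libraries, so their direction is not independent evidence, and the ESC library has no replicate. Over all tested genes, the Spearman correlation with the ESC library (across genes, which are not independent replicates) was 0.914 ± 0.00474 (SD, n = 2) in WT and 0.848 ± 0.00713 in KO at day 10, against 0.847 ± 0.0222 and 0.822 ± 0.0275 at day 0. The ESC library had the shortest mean transcript length weighted by counts, 2892.5 bases, against 3116.5 (A) and 3916 (B) in WT at day 0. At day 10 WT had 3437 and 3388 bases and KO 3360 and 3325. The day 0 correlation was higher in A than in B, at 0.863 against 0.831 in WT and 0.842 against 0.803 in KO. The correlations were not corrected for length. Over genes of at least 10 CPM, KO replicate A was at 0.736 at day 0 and 0.733 at day 10, and replicate B at 0.633 and 0.720 (means 0.684 and 0.727). KO cells at day 10 were closer to WT cells at day 2 (0.972) than to WT cells at day 10 (0.906). The pre-iPSC-high share was 43.5% in WT without WT day 0 A, and in KO 15.96% without KO day 0 A and 7.35% without KO day 0 B.

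**Figure D3:**
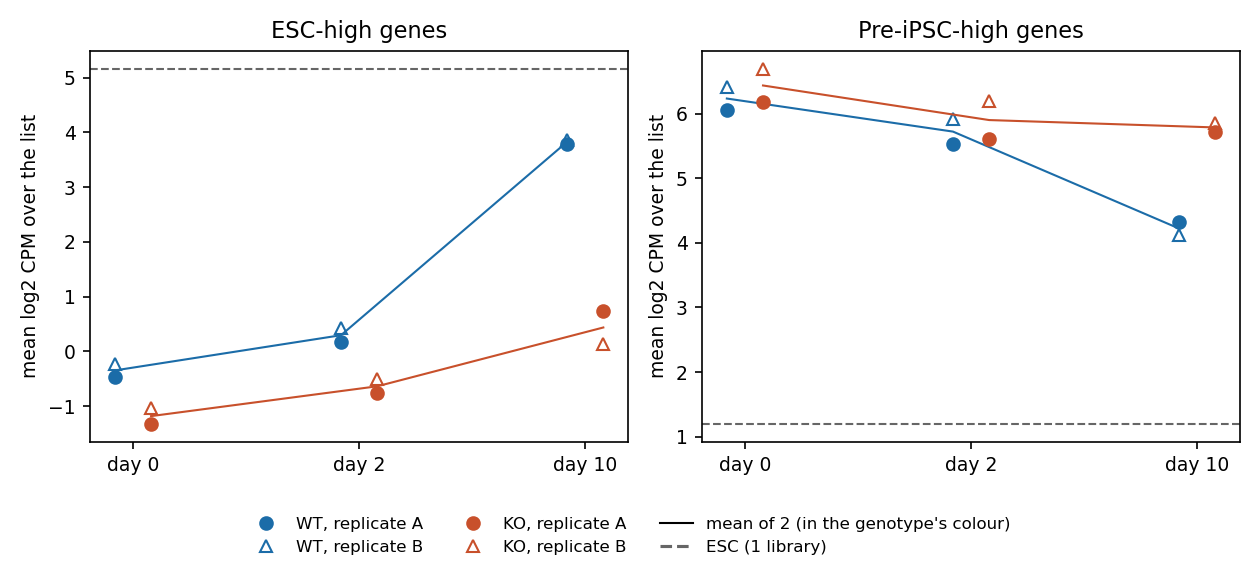
Mean log2 CPM of the 397 ESC-high genes and of the 164 pre-iPSC-high genes in each library, with the single ESC library for comparison. WT at day 10 had covered 75.7% of the ESC-high distance and KO 25.5%.

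The gene totals of the reprogramming factors cannot tell a transgene from the chromosomal copy. Pou5f1 fell in WT from 5731 ± 2397 CPM at day 0 to 1264 ± 92.8 at day 10 (log2 fold change -2.16, FDR = 0.0146), Klf4 from 1437 ± 810.1 to 321 ± 22.8 CPM (-2.14, FDR = 0.0312), and Myc from 1153 ± 573 to 137 ± 15.97 CPM (-3.06, FDR = 0.00507). Sox2 was not called in any comparison. The Pou5f1 call was lost without WT day 10 A (adjusted p = 0.0987), WT day 0 B (0.08) or WT day 10 B (0.084). The Klf4 call was lost without WT day 10 A (0.134), WT day 0 B (0.185), WT day 10 B (0.157), KO day 10 A (0.0534) or KO day 10 B (0.0533). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were present in all 12 pre-iPSC libraries. Among them, Kdm5d fell in WT between day 2 and day 10 (-0.92, FDR = 0.0311) and Uty fell in KO by day 10 (-0.63, FDR = 0.0478). Imprinted genes went both ways in WT by day 10, with 9 of 20 higher and 4 lower (9 and 5 adjusted over the list alone; adjusted p = 0.0904), and 4 were higher in KO (5 adjusted over the list alone). H3K9 methylation enzymes and readers were lower in 5 of 21 cases and higher in 1 in WT (5 and 1 adjusted over the list alone; 0.0868), and lower in 2 and higher in 1 in KO (0 and 1 adjusted over the list alone). DNA methylation genes were higher in 4 and lower in 4 of 17 in WT and higher in 4 in KO, with the same counts adjusted over the list alone. In WT the median and the test pointed down for that list and the mean pointed up. Hypoxia targets were higher in 3 and lower in 3 of 20 in WT, where the mean again differed in sign from the median and the test, and higher in 2 in KO (3 and 3 in WT and 1 in KO adjusted over the list alone). Markers of the primed epiblast (4 of 7 higher and 2 lower in WT), immune cells (2 of 6 higher and 1 lower), endothelium (4 of 10 higher and 1 lower) and fibroblasts were not called as lists in either genotype by day 10.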

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

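The tests of germline genes, of genes on at day 2, of a small share of RNA among silent genes and of a difference fixed at day 0 were chosen only after the result was seen, and the length tests were chosen after the data were examined but before their own results were.

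A test of the difference between genotypes brought up the responses at day 2, with 28 genes, and at day 10, with 1798. At day 2 Peg10 (interaction log2 3.02) and Igf2 (-3.43) differed, as did the lists of epithelial (camera adjusted p = 0.00424), Wnt (9.52e-06), trophectoderm (3.8e-08) and neural genes (0.00388). With an estimated correlation the epithelial (0.476), Wnt (0.476) and neural calls (0.152) were lost. At day 10 the lists were germline genes (2.77e-16), interferon response (3.8e-07), ERK targets (0.000564), genes of the 2-cell stage (0.00104), cholesterol synthesis (0.0011), primitive endoderm (0.0314) and neural markers (0.0394). Of these, ERK targets (0.226), genes of the 2-cell stage (0.0636), cholesterol synthesis (0.126), primitive endoderm (0.493) and neural markers (0.21) lost their calls with an estimated correlation, and neural markers also with the replicate block (0.0685). The genes were Peg10 (6.16), Wnt8a (7.83), Etv4 (4.13), Mtap2 (3.48), Sox1 (3.14) and Zeb2 (2.56), with a more positive change in KO, and Dppa4 (-6.07), Asns (-3.27), Igf2 (-3.05), Trib3 (-2.99), Fgf4 (-2.67) and Insig1 (-1.92), with a more negative one. Of these, Peg10 and Mtap2 had started lower in KO at day 0 (-5.27 and -3.61). In the ESC library, which entered none of the fits, 1 gene reached 10 CPM with at most 3 counts in all 12 pre-iPSC libraries. It was Tmem59l, at 10.5 CPM with 2 counts, chosen after its values were seen.

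The lower level of ESC-high genes in KO than in WT at day 10 was weighed first. A correction for transcript length left the median log2 fold change of the 397 genes in KO against WT at -3.74 (quartiles -4.74 and -2.60, -3.73 without it), which argues against uneven recovery of long transcripts as its whole cause. The day 10 libraries differed little in mean transcript length weighted by counts (3437 and 3388 bases in WT, 3360 and 3325 in KO). The correction therefore had little to remove in this comparison. For a difference fixed at day 0, the median interaction was -2.43 (quartiles -4.10 and -0.81), with 122 genes called lower and 12 higher. The list was chosen to be low at day 0 in both genotypes (mean log2 CPM -0.35 in WT and -1.18 in KO, against 5.17 in the ESC library). That choice limits how large a day 0 difference could be, so the test favoured this outcome and cannot decide. The values show only that the difference grew after day 0 for most of these genes. Left open is a small share of RNA from cells like those of WT at day 10: over 73 ESC-high genes that were silent in KO before and whose WT level at that share would give at least 20 counts in KO, the ratio of KO to WT at day 10 had a median of 3.18% and an interquartile range of 0.953 log2 units. Over 94 silent ESC-high genes with at least 10 CPM in WT the range was 1.05, and the 2 values lie on either side of the bound set for such a share, so that the test could not decide. For genes already on at day 2 the test could not decide (187 genes, median gain 5.79%, quartiles 1.59 and 16.02%). An effect of the genotype, or of the line that carries it, in all cells stays open, since bulk RNA cannot tell weak expression everywhere from full expression in a few cells.

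For germline genes a share that is the same for all genes is argued against, but only weakly. The test set a pooled ratio of 7 genes, in which genes high in WT weigh most, against a median of single-gene ratios. In KO at day 10, 7 germline genes silent before reached a pooled 1.64% (A) and 0.460% (B) of their WT level, against medians of 4.67% and 1.72% for 94 silent ESC-high genes, and the larger quotient was 0.351. Silent genes outside the ESC-high list (109 genes) had medians of 3.56% and 1.61%, with a wider interquartile range of 1.68 log2 units against 1.05. Cells in which germline genes were not yet on could still supply the other genes, which was not tested.

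The replicate letters split the libraries of days 0 and 2. Genes of short transcripts lay on the A side: the A minus B difference correlated with transcript length at -0.506 and -0.401 at day 0 in WT and KO and at -0.387 and -0.410 at day 2, against 0.0719 and 0.0517 at day 10. The 70 ribosomal protein genes were higher in A by medians of 1.28 and 1.34 log2 units at day 0 in WT and KO. At day 2 the medians were 1.03 in WT and 1.45 in KO, and at day 10 -0.10 in both genotypes. After the length trend was removed the lowest of the 6 pair correlations was still 0.692 (0.741 before), which argues against length recovery as the whole cause. A batch of library preparation shared by days 0 and 2 is not named in the labels and stays open, and no biological explanation was tested.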

How the results depend on the processing

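The block at days 0 and 2 only, the length correction and the fits with 1 replicate letter at days 0 and 2 were tests chosen only after the main results were seen. The length tests were set before their own results. No log2 fold change of a named gene and no list call changed sign under any alternative run, but the balance of higher and lower genes did. The fits with replicate A or B alone have a single library per group at days 0 and 2 and take their spread from day 10, where the replicate chi-square per degree of freedom was 9.07 in WT and 11.4 in KO, against 147 to 285 at days 0 and 2. For KO against WT the balance turned at day 0 with replicate B alone (52.8% higher, 32.5% in the main fit) and at day 2 with replicate B alone and the block at days 0 and 2 (50.9% and 51.4%, against 41.1%). For the day 10 interaction, at 50.6% more positive in the main fit, it turned with RLE factors (47.8%), DESeq2 (46.8%), a 2-fold minimum (49.7%), only the libraries compared (48.9%) and without WT day 10 B (47.9%), KO day 0 A (46.97%) or KO day 10 A (49.9%). The block at days 0 and 2 brought the share of higher genes to 51.6% for WT day 2 (62.7% in the main fit) and 51.9% for KO day 10 (65.7%), and replicate B alone to 50.1% for WT day 10 against day 2 (62.1%), 51.6% for KO day 10 and 48.8% for KO against WT at day 10 (38.5%). RLE factors, no filter and a 2-fold minimum kept all 11 counts of changed genes within 1.5 times. In the order WT day 2, WT day 10, WT day 10 against day 2, KO day 2, KO day 10, KO day 10 against day 2, KO against WT at days 0, 2 and 10, and the interactions at days 2 and 10, the block at days 0 and 2 only called 4318, 9412, 8984, 4225, 6840, 5328, 4360, 5252, 9136, 1109 and 6388 genes, replicate A alone 1608, 8705, 7896, 1770, 5888, 3282, 1936, 2584, 8966, 122 and 4469, and replicate B alone 1873, 8648, 8288, 1801, 6963, 6667, 2460, 3344, 8956, 128 and 4533. The planned replicate block gave 1433 (WT day 2), 1478 (KO day 2), 3284 (KO day 10), 1152 (KO day 10 against day 2), 1792, 2293 (KO against WT at days 0 and 2), 91 and 2942 (interactions). It changed no other call of a list than the 4 given beside their results. DESeq2 gave 1455 (WT day 2), 1541 (KO day 2), 1341 (KO day 10 against day 2), 1792 (KO against WT at day 0), 223 and 2746 (interactions), and length-corrected offsets 784 (KO day 10 against day 2) and 73 (interaction at day 2). With only the libraries compared, the counts were 119 (WT day 2), 0 (KO day 2, with 1199 at an unadjusted p under 0.05 in edgeR), 1042 (KO day 10), 0 (KO day 10 against day 2, with 1382), 141 and 79 (KO against WT at days 0 and 2) and 0 (interaction at day 2, with 708), but 8554 for KO against WT at day 10. These fits have fewer degrees of freedom and take their spread from the compared libraries alone, whose replicates differed less at day 10. Which of these moved the counts was not tested.

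Leaving out 1 library at a time, with a lone library assumed to vary like the other groups, gave 193 to 775 genes for WT day 2, 3000 to 5349 for WT day 10, 2304 to 4655 for WT day 10 against day 2, 453 to 753 for KO day 2, 1005 to 2267 for KO day 10, 112 to 373 for KO day 10 against day 2, 547 to 1232, 647 to 1458 and 2620 to 5009 for KO against WT at days 0, 2 and 10, and 0 to 14 and 925 to 1975 for the interactions. Kdm3b at day 0 ranged from -2.32 to -1.71 and lost its call in 2 of these fits, and with only the libraries compared its log2 fold change of -1.96 at day 0 and -2.72 at day 2 lost their calls. It kept its call in the other 59 cases. Genes higher in both genotypes at day 2 numbered 391 with the block, 1198 with the block at days 0 and 2, 456 and 485 with A and B alone and 89 to 211 without 1 library, and those lower in both 296, 1085, 317, 350 and 31 to 101, and 226 with the length correction. At day 10 those higher in both numbered 1972, 1781 and 1912 with the block at days 0 and 2, A alone and B alone and 448 to 825 without 1 library, and those lower in both 1803, 1582, 2064 and 114 to 390, 684 with the block and 205 at 2-fold in both. WT had covered 77.4% of the ESC-high distance with 16-fold lists. It had covered 44.1%, 35.8% and 43.5% of the pre-iPSC-high distance with 4-fold lists, 16-fold lists and a list from KO at day 0, and 38.03 to 43.5% without 1 library. KO had covered 5.63% of it with a list from WT at day 0 and 7.35 to 15.96% without 1 library. Over genes of at least 10 CPM the correlations with the ESC library were 0.856 (WT) and 0.727 (KO) at day 10.

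Of 94 list calls, 78 were lost with an estimated correlation, 7 with fry, 4 with the block, 1 with RLE factors and 22 without some library. Of 189 named gene calls, 44 were lost with only the libraries compared, 1 with DESeq2 and 8 without some library (those named beside their values, and Tac2 in WT at day 2, Fndc1 in KO at day 10, and Pcdh17 and Dll1 in KO against WT at day 0). At this depth 3 counts over a group amount to 0.0658 to 0.0918 CPM in pre-iPSCs, the floor used for genes at 0 counts.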

Other observations

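No test here was planned: the comparisons of the ESC library with WT at day 10 were chosen only after the results were seen.

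The ESC library, which entered no test, was set beside WT pre-iPSCs at day 10. Dnmt3b, at 585 CPM, and Dnmt3l, at 317 CPM, stood well above the 69.1 ± 4.93 and 19.3 ± 1.77 CPM of WT at day 10. Dazl was at 8.71 CPM in ESCs against 202 ± 20.7, Irf7 at 0.374 CPM against 25.3 ± 6.87 and Isg15 at 2.35 CPM against 36.8 ± 0.654. The smooth muscle genes Tagln (348 CPM in ESCs) and Acta2 (123 CPM) were at 6.22 ± 3.89 and 8.75 ± 3.79 CPM in WT at day 10.

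As lists, interferon response genes were lower in the ESC library than in WT at day 10 (median log2 difference -3.11), with 17 of 21 at least 2-fold lower, a median at percentile 0 of 10000 random lists matched on expression. Keratinocyte-like markers had a median of -2.02 (percentile 0.06), with 7 of 11 at least 2-fold lower. Primed epiblast markers had a median of 2.00 (percentile 99.98), epithelial genes 1.20 (99.99), fibroblast genes 0.90 (100), neural markers 0.90 (99.91), cholesterol synthesis genes 0.68 (99.99) and cell cycle genes 0.50 (99.25). ERK targets had a median of 1.25 (percentile 100), with 13 of 19 at least 2-fold higher. Germline genes were mixed, with 8 of 19 at least 2-fold lower and 5 higher (median -0.65, percentile 26.5). The 18 naive genes had a median of -0.43 (percentile 5.97) and the 19 general pluripotency genes one of 0.65 (99.87). These values describe 1 ESC library, whose treatment label reads AA+2i at 0hr, and carry no replicate error. They were not corrected for its shorter mean transcript length weighted by counts, 2892.5 bases against 3437 (A) and 3388 (B) in WT at day 10.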
